A study of Homo sapiens with 6 samples.

How the data were processed

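Poly(A)-selected RNA of THP1 cells was sequenced in 6 libraries, 3 from control cells and 3 from cells given a lentivirus that overexpresses hsa_circRNA_103124. The series description gives the controls a control lentivirus, while the sample labels give their genotype only as WT. Without that lentivirus the fold changes would include any effect of transduction. Per the labels' protocols, mRNA was enriched with oligo(dT) beads, libraries were made with a NEBNext Ultra RNA kit and sequenced as paired ends. Per the submitters' processing notes, bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.2 and the hg38 build were used; the annotation and the tool behind the authors' comparison are not given in the sources used here. The labels do not say whether the 3 libraries of a group came from separate transductions or cultures, so p-values measure the spread between these libraries, which may be technical.

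The deposited gene table holds a normalized signal per gene, meaning read counts that the authors divided by 1 size factor per library. Every value was a whole multiple of the smallest value of its library: 100% of the values came out whole within 0.001 of a read, so the reads could be recovered. The deposited transcript table holds the same normalized signal for RefSeq transcripts, and its recovered reads sum to 4.56 to 4.71 times those of the gene table, so a read was counted in several transcripts of a gene. The authors also deposited a log2 fold change, a p-value and a q-value per gene and transcript, and lists of those they called different. Coordinates are those of the authors' table, on hg38.

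The planned test was edgeR's quasi-likelihood test on raw counts. Since the table held normalized values, the test fixed for that case before the data were examined was used: limma (version 3.58.1, R 4.3.3) with a mean trend and robust variances on log2(value + 1), with group as the only term. Fold changes are on that scale, which understates the change of genes with low values. Genes with at least 10 normalized counts in at least 3 libraries were tested, a filter set once the unit was known in place of the planned one for raw counts, and 15916 of the 19614 in the table passed it. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Transcripts were tested in the same way. On the recovered reads, edgeR (version 4.0.16) with TMM scaling, added after the unit was known, called 5742 genes, 2799 higher and 2943 lower. In simulated data for this comparison, with 200 changed genes among 15909, limma recovered 59.7% of the 1.5-fold changes, 98.5% of the 2-fold changes and 100% of the 4-fold changes, and 6.52% of its calls were false. The changed genes were drawn only from those with a mean well above the filter. Simulated genes varied independently, with a common dispersion trend for both groups. The 200 changed genes are also far fewer than the 5793 called in the real data. An adjusted p under 0.05 therefore stood for a stricter p-value in the simulation. For these reasons the rates need not hold for the real comparison, for genes with low values or for the spread of the real libraries.

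Gene lists, 22 in number, were fixed before the data were examined and matched by symbol or by an older symbol. Of these, 21 had at least 3 tested members. The list of mitochondrially encoded genes had no member matched by symbol and is not analysed here, although 19 tested genes lay on chromosome M. Lists were tested with camera on the log2 values at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, each adjusted over the 21 lists. A rule for the genes named in the text was also fixed in advance. It took, first, the 10 genes with the largest rise and the 10 with the largest fall among those with an adjusted p under 0.05, an average of at least 3 log2 CPM and no overlap between the groups. Second, it took up to 4 members of each list past the threshold by smallest p, or the 1 with the smallest p where none passed. Last, it took TLR4, AKT2, NFKB1, RELA, TNF, IL1B, IL6, CXCL8, CD14, CD86, MRC1 and CD163 in any case. List members named without a value, and B2M, CD74, PSMB8 and CIITA, were chosen after their values were seen. A test of single values between 3 and 3 libraries cannot give an exact permutation p below 0.1, so significance rests on limma, which pools the spread over genes.

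Library depth was 20642100 to 24814893 recovered gene reads, and the median SD between libraries was 0.176 on the log2 scale in the controls and 0.107 with overexpression. No pair of libraries of a group agreed within counting noise: chi-square per gene was 2.398 in the closest pair. As labelled, the kit does not mark strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Near-identical genes (HLA genes, CCL3 and CCL3L3, HSPA1A and HSPA1B) can exchange reads, and their values are uncertain to that extent. The overexpressed circRNA could not be matched to a row by identifier or coordinates, and no value is given for it. Its overexpression was therefore not checked in these poly(A)-selected libraries. Alternatives covered the scaling of libraries (in edgeR and in limma), the filter, the pseudocount, edgeR, limma-voom and DESeq2 (version 1.42.0) on the recovered reads, the replicate number as a term, leaving out each library, a correction of each library for GC content and transcript length, and thinning to equal depth.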

Results

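The transcriptome of THP1 cells, a human acute monocytic leukaemia line widely used as a model of monocytes, was compared between cells that overexpressed hsa_circRNA_103124 from a lentivirus and cells given, per the series description, a control lentivirus, with 3 libraries each. The control libraries held 23411832, 20642100 and 24814893 gene reads, and the overexpressing libraries 21656033, 23677729 and 20827161. The first principal component of log2 expression carried 67% of the variance and separated the groups. The second carried 14.1% and set control replicate 2 (score -29.3) apart from control replicates 1 and 3 (15.9 and 26.8), while the overexpressing libraries lay between -7.09 and 0.645. Correlations across genes were 0.9915 to 0.9931 among overexpressing libraries and 0.9786 to 0.9913 among controls, with the lowest between control replicates 2 and 3, against 0.9538 to 0.9762 between groups.

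The comparison asked which genes differ in expression when the circRNA is overexpressed. Of 15916 genes tested, 2964 were higher and 2829 lower in overexpressing cells (limma, adjusted p under 0.05), and 491 and 778 of these by at least 2-fold. The top rises included TXNIP, which encodes the thioredoxin-interacting protein (chromosome 1, 145992435 to 145996579): its normalized count went from 1177 ± 292 (SD, n = 3) to 5845 ± 331 (n = 3), a 5.06-fold rise (log2 2.34, SE 0.15, limma adjusted p = 0.000108). The long noncoding RNA LOC102724908 (chromosome 19, 28606688 to 28615229) rose 5.75-fold, from 872 ± 162 to 4966 ± 124 (SD, n = 3). The deepest falls included MMP9, the secreted gelatinase (chromosome 20, 46008908 to 46016561), from 869 ± 64.1 to 153 ± 38.5 (SD, n = 3), which is 5.74-fold (log2 -2.52, SE 0.16, limma adjusted p = 8.93e-05). The carbonic anhydrase gene CA2 (chromosome 8, 85464007 to 85481493) fell from 55948 ± 12911 to 14954 ± 1535 normalized counts (log2 -1.88, SE 0.17).

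Other genes with large rises were UGT3A2 (a UDP-glycosyltransferase gene, 5.65-fold), LINC02870 (log2 2.21), LOC101928429 (2.03, inside the span of MAP3K5), UNC5C (a netrin receptor gene, 2.01), the adhesion receptor gene ADGRG5 (2.01), GAPT (1.88), NCOA5 (a nuclear receptor coactivator gene, 1.86) and MIR1915HG (1.85). Those with large falls were DDIT3 (log2 -2.83), HLA-DRA (-2.46), ADGRB2 (-2.36), SGSH (a lysosomal sulfatase gene, -2.21), CRELD1 (-2.07), NPTX1 (-1.94), the heat-shock cochaperone gene DNAJB5 (-1.89) and the Notch ligand gene DLL1 (-1.84). Over all tested genes, 51.8% had no overlap between the groups, where chance gives 10%. The size of the DDIT3 fall varied with the controls, whose counts were 1207, 4761 and 576 against 179, 227 and 227 with overexpression. It was log2 -1.99 without control replicate 2 (limma adjusted p = 0.00894) and -3.51 without control replicate 3 (0.0192). The call ended without control replicate 1 (log2 -2.98, adjusted p = 0.0671) and without overexpressing replicates 1, 2 and 3 (-2.71, -2.88 and -2.88, adjusted p = 0.0757, 0.0982 and 0.0851), where the fall was of similar size. It also missed the threshold with no filter (0.0677) and with limma-voom (0.116). The calls of CRELD1 ended without overexpressing replicate 2 (limma adjusted p = 0.0527) or 3 (0.0537), and that of LINC02870 without overexpressing replicate 3 (0.0505). The number of changed genes was 3573 and 3542 without overexpressing replicates 2 and 3. With upper-quartile scaling in edgeR the split was 2360 higher and 3423 lower.

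**Figure D1:**
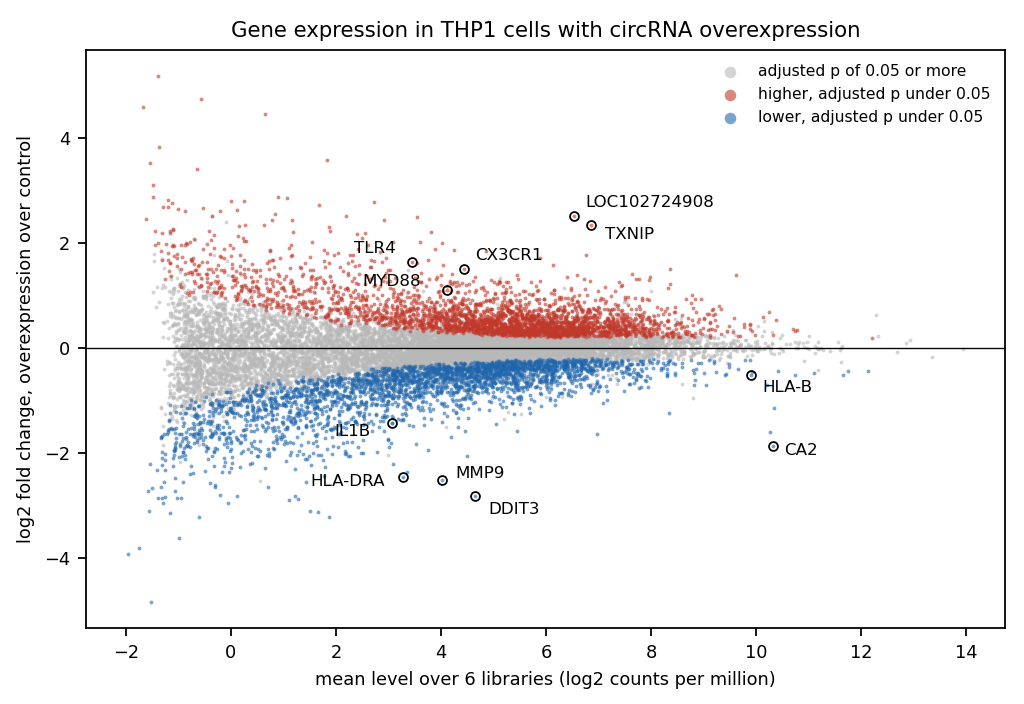
Log2 fold change of overexpression over control (vertical axis) against mean level in log2 CPM (horizontal axis) for the 15916 genes tested; each point is a gene, red where higher and blue where lower at a limma adjusted p under 0.05, grey otherwise, and circles mark named genes. TXNIP lies at 2.34 and MMP9 at -2.52, and changed genes are seen at every level of expression.

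Genes of the TLR4 pathway, through which monocytes sense lipopolysaccharide, included rises of the receptor and its adaptor MYD88. TLR4 itself (chromosome 9, 117704403 to 117724735) went from 146 ± 63.4 to 429 ± 39.6 normalized counts (SD, n = 3), a 3.13-fold rise (log2 1.64, SE 0.28, limma adjusted p = 0.00341). The adaptor gene MYD88 rose 2.15-fold (263 ± 32.4 to 565 ± 24.7), the kinase genes IKBKE, IRAK1 and IKBKB rose by log2 1.09, 0.81 and 0.49, and NFKB1, which encodes an NF-kB subunit, rose by 0.37 (SE 0.09, adjusted p = 0.0131). The co-receptor gene CD14 fell from 175 ± 19.8 to 112 ± 13.7 (log2 -0.64, SE 0.16, adjusted p = 0.0116). RELA, the other main NF-kB subunit gene, stood at log2 0.16 (SE 0.09, adjusted p = 0.165). Of 27 tested TLR4 and NF-kB signalling components, 7 were higher (also RELB), 3 lower (CD14, NFKB2 and TRAF6) and 17 did not pass, with the same counts when adjusted over the list alone. As a set they did not stand apart from other genes (median log2 0.13, camera adjusted p = 0.489). Without control replicate 2 the list had 11 higher members. It had 1 lower member without control replicate 1 or overexpressing replicate 3, and 0 without overexpressing replicate 2. The NFKB1 call ended without control replicate 1 (adjusted p = 0.0594) or overexpressing replicate 1 (0.0562), and the CD14 call without overexpressing replicate 2 (0.0532) or 3 (0.0526).

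Among NF-kB target genes, falls outnumbered rises. Of 26 tested, 12 were lower, 1 was higher (NFKBIA, the inhibitor gene) and 13 did not pass, and the counts adjusted over the list alone were the same. The cytokine gene IL1B (chromosome 2, 112829751 to 112836843) fell from 304 ± 25.5 to 115 ± 31.2 normalized counts (SD, n = 3; log2 -1.43, SE 0.20, limma adjusted p = 0.00076). EBI3, a subunit gene of heterodimeric cytokines, fell by log2 -2.04, the early-response gene IER3 by -2.05 and SOD2, the mitochondrial superoxide dismutase gene, by -0.82. The median of the list was log2 -0.32, and the set test missed its threshold (camera adjusted p = 0.057; p = 0.413 with an estimated correlation). It passed without control replicate 2 (adjusted p = 0.0466), control replicate 3 (0.0298) or overexpressing replicate 1 (0.00312), whose list mean, -0.10 against the control mean, lay above those of overexpressing replicates 2 and 3 (-0.51 and -0.66). The set test did not pass without control replicate 1 (camera adjusted p = 0.0624), overexpressing replicate 2 (0.0995) or overexpressing replicate 3 (0.185, with a median of -0.19). The NFKBIA call ended without control replicate 1 or 2, or overexpressing replicate 1 or 2, and without overexpressing replicate 3 there were 2 higher members. TNF stood at log2 -0.30 (SE 0.23, limma adjusted p = 0.323) and passed without overexpressing replicate 1 (-0.59, adjusted p = 0.0299). CXCL8 stood at -0.21 (SE 0.33, adjusted p = 0.639) and at 0.11 without control replicate 2. IL6 had 0 to 5 reads per library and was not tested.

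**Figure D2:**
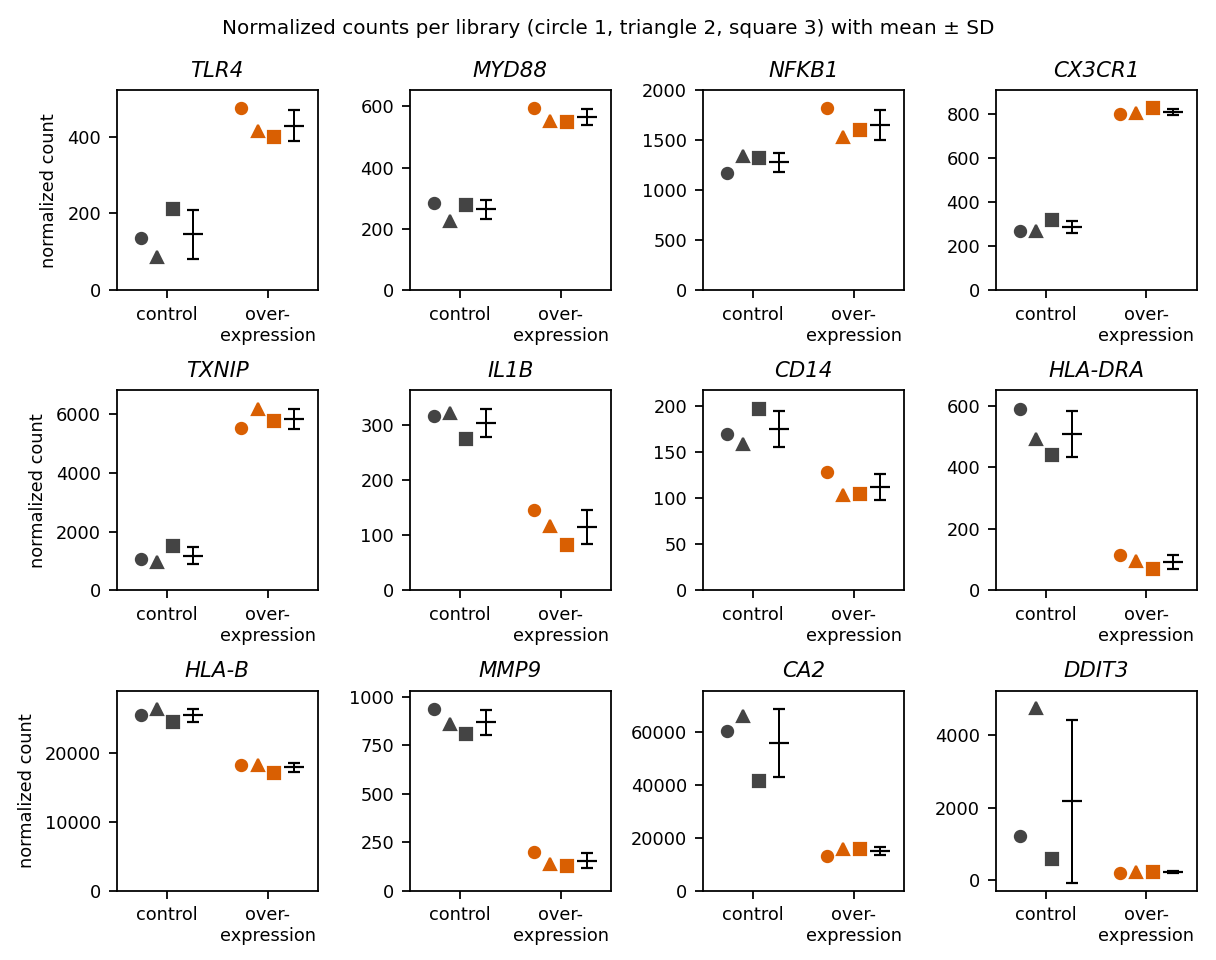
Normalized counts (vertical axes, linear) of 12 named genes in each library of the control (grey) and overexpressing (orange) groups; the symbol gives the replicate number and the bars show the mean ± SD of 3 libraries. TLR4 rose from 146 to 429 on average, while control replicate 2 stands out at 4761 for DDIT3.

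Macrophage marker genes changed in both directions within each polarization type. Among 15 tested M1-type markers, 3 were higher (FCGR1A, CXCL10 and IRF5) and 5 lower (IL1B, GBP5, SOCS3, CCL5 and CCR7), with 3 and 7 when adjusted over the list alone. FCGR1A, the high-affinity IgG receptor gene, rose by log2 0.70 (SE 0.12), the guanylate-binding protein gene GBP5 fell by -1.28 (SE 0.26), and SOCS3, a feedback inhibitor gene of cytokine signalling, fell by -0.51 (SE 0.11). Among 13 M2-type markers, 2 were higher (F13A1 and CCL22) and 4 lower (FCER2, PPARG, TGFBI and MERTK), with 2 and 5 when adjusted over the list alone. F13A1, the coagulation factor XIII A chain gene, rose by log2 1.28 (SE 0.27), and PPARG, the lipid-activated nuclear receptor gene, fell by -0.56 (SE 0.14). Neither list passed as a set (camera adjusted p = 0.489 and 0.555). CD86 stood at log2 -0.99 (SE 0.40, limma adjusted p = 0.0764) and passed without overexpressing replicate 2 (0.0479) or with the replicate number as a term (0.045). CD163 had 2 to 19 reads per library and was not tested, and MRC1 is not analysed here. Without overexpressing replicate 1 the M1-type list had 1 higher member, and without overexpressing replicate 3 or control replicate 1 it had 3 lower members. The M2-type list had 1 higher member without any of the overexpressing replicates and 2 lower ones without overexpressing replicate 3. The TGFBI call ended without overexpressing replicate 1 (adjusted p = 0.0702) or 3 (0.0596).

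Several chemokine receptor genes rose. CX3CR1, the fractalkine receptor gene (chromosome 3, 39263494 to 39281735), went from 286 ± 27.0 to 810 ± 13.8 normalized counts (SD, n = 3; log2 1.51, SE 0.10, limma adjusted p = 8.93e-05). CCR2, the receptor gene for the monocyte chemoattractant CCL2, rose 2.98-fold, and CXCR2 rose 2.67-fold, while the chemokine gene CCL3, whose reads can be shared with CCL3L3, fell by log2 -0.84. Of 18 tested chemokines and receptors, 8 were higher and 3 lower (CCL3, CCL3L3 and CCL5), or 8 and 4 when adjusted over the list alone (median log2 0.06, camera adjusted p = 0.489). Among 32 monocyte and macrophage identity genes, 11 were higher and 7 lower (12 and 8 over the list alone; median 0.09, adjusted p = 0.555). CSF1R, the receptor gene for macrophage colony-stimulating factor, rose by log2 0.87 (SE 0.11), as did LST1 (0.85, SE 0.09). The integrin genes ITGAM and ITGB2, which encode the chains of complement receptor Mac-1, fell by -0.74 (SE 0.10) and -0.52 (SE 0.07). Leaving out any overexpressing library left 5 higher chemokine-list members, and 1 was lower without overexpressing replicate 2 and 0 without control replicate 1 (the CCL3 adjusted p was then 0.0553). The chemokine median was -0.04 without overexpressing replicate 1, 0.27 without overexpressing replicate 3, 0.20 without control replicate 2 and 0.31 after the GC and length correction, and the identity median -0.01 without control replicate 2. The identity list had 7 higher members without overexpressing replicate 1, and 4 and 11 lower members without overexpressing replicate 2 and control replicate 2.

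Antigen presentation genes were lower as a set. Of 23 tested, 14 fell, 1 rose (PSMB8) and 8 did not pass, or 15 and 1 when adjusted over the list alone, with a median of log2 -0.49 (camera adjusted p = 7.4e-05). With an estimated correlation the camera p was 0.0545 (adjusted p = 0.934), and fry gave p = 0.000528 (adjusted p = 0.0111). The fall lay in the HLA genes, of which 12 of 13 in the list fell, and in their partners B2M (log2 -0.43, SE 0.07, limma adjusted p = 0.00122) and CD74 (-0.49, SE 0.08), which encode the light chain of class I molecules and the class II invariant chain. HLA-DRA (chromosome 6, 32439887 to 32445046) fell from 509 ± 76.3 to 93.1 ± 23.3 normalized counts (SD, n = 3; log2 -2.46, SE 0.19, adjusted p = 0.000126). The class II gene HLA-DPB1, which overlaps HLA-DPA1, fell by -2.65 (SE 0.33) from a low level of 40.8 ± 1.08. The abundant class I gene HLA-B fell from 25498 ± 932 to 17908 ± 641 (log2 -0.51, SE 0.07) and HLA-E by -0.73 (SE 0.08). Of the 10 members outside the HLA family, B2M and CD74 were the 2 that fell, and the PSMB8 call (log2 0.28, adjusted p = 0.04) ended without control replicate 1 (adjusted p = 0.0787) or overexpressing replicates 1, 2 or 3 (0.0834, 0.15 and 0.103), with upper-quartile (0.076) or library-size scaling in edgeR (0.0682) or limma (0.0629), after correction for GC content and length (0.0529) and with the replicate number as a term (0.0579). Without control replicate 2 there were 2 higher members, and CIITA, which lies outside the HLA family, also passed as lower. CIITA stood at log2 -0.704 there (limma adjusted p = 0.000437), against -0.475 (adjusted p = 0.101) with all libraries. The number of lower members was 13 to 15 whichever library was left out.

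Interferon-stimulated genes did not move together: of 39 tested, 3 were higher and 5 lower (among them IFI6 and HERC5), or 3 and 4 when adjusted over the list alone (median log2 0.04, camera adjusted p = 0.804). IFIT3 rose from 39.6 ± 10.7 to 150 ± 57.3 normalized counts (SD, n = 3), and HERC6 rose by log2 1.76 (SE 0.27) and RSAD2, the viperin gene, by 0.74 (SE 0.17). Overexpressing replicate 1 stood apart, with a list mean of 0.42 against -0.07 in each of the other overexpressing libraries, and the median turned to -0.13 without it (0.15 without overexpressing replicate 2). Of 15 inflammasome genes, NAIP (log2 0.89, SE 0.13) and PYCARD (1.08, SE 0.16), which encode a sensor and the adaptor ASC, rose, and IL1B (-1.43) and NLRP1 (-0.72, SE 0.25) fell, or 2 and 1 when adjusted over the list alone (camera adjusted p = 0.936); the median (-0.01) pointed down, the mean (0.00312) and the set test up. The inflammasome median turned to 0.05 without control replicate 2, 0.02 without overexpressing replicate 2 and 0.01 after the GC and length correction, and the set test pointed down without control replicate 1 or overexpressing replicate 1. The NLRP1 call ended whichever library was left out (adjusted p from 0.0544 to 0.15), leaving 1 lower member, and with no filter (0.0534), DESeq2 (0.107) or the replicate number as a term (0.0708). Without control replicate 2 there were 5 higher interferon-stimulated and 4 higher inflammasome genes, and there was 1 lower interferon-stimulated gene without control replicate 1 and 2 without overexpressing replicate 2 or 3.

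Components of the PI3K-AKT-mTOR pathway, which couples receptors to growth and survival, had more rises than falls, by small amounts. Of 31 tested, 13 were higher and 3 lower (FOXO1, PHLPP2 and RHEB), with the same counts when adjusted over the list alone, a median of log2 0.18 and a camera adjusted p of 0.0602 (p = 0.358 with an estimated correlation). The S6 kinase gene RPS6KB2 rose by log2 0.52 (SE 0.09), TSC1, which encodes an inhibitor of mTOR signalling, by 0.52 (SE 0.09), RPTOR by 0.42 (SE 0.08) and PIK3R1 by 0.49 (SE 0.10). AKT2 stood at log2 0.21 (SE 0.09, limma adjusted p = 0.0887). The set passed without control replicate 3 (camera adjusted p = 0.0298), but higher members numbered 6 without control replicate 1 and 5, 4 and 5 without overexpressing replicates 1, 2 and 3. There was 1 lower member without control replicate 1 or 3, or overexpressing replicate 2 or 3. Among 35 autophagy genes, 3 were higher (WIPI2, ATG5 and ATG14) and 5 lower (WIPI1, GABARAPL1, CALCOCO2, MAP1LC3B and ULK2), or 2 and 4 when adjusted over the list alone (median -0.01, adjusted p = 0.713). WIPI1 fell by log2 -1.47 (SE 0.22) and GABARAPL1 by -1.08 (SE 0.16). The autophagy list had 3 lower members without control replicate 1 or overexpressing replicate 1 or 3, and 1 higher, with a median of 0.00329, without overexpressing replicate 3.

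Genes of the unfolded protein response were lower as a set only with camera at the preset correlation, and control libraries differed widely from each other. Of 21 tested, 8 fell, 1 rose (VLDLR) and 12 did not pass, or 10 and 1 when adjusted over the list alone (median log2 -0.69, camera adjusted p = 0.00113). With an estimated correlation the camera p was 0.355 (adjusted p = 0.934), and fry gave p = 0.117 (adjusted p = 0.222). Against the control mean, the list mean was -0.25, 0.82 and -0.57 in control replicates 1, 2 and 3 and -0.85, -0.79 and -0.81 in the overexpressing libraries. The share of gene reads from mitochondrial rRNA was 1.088%, 1.326% and 1.141% in control replicates 1, 2 and 3 and 0.9825%, 1.061% and 1.03% in overexpressing replicates 1, 2 and 3. SDF2L1, which encodes an endoplasmic reticulum chaperone partner, fell from 3604 ± 919 to 2191 ± 31.3 normalized counts (SD, n = 3; log2 -0.69, SE 0.15, limma adjusted p = 0.00848), and EDEM1, a gene of endoplasmic reticulum associated degradation, fell by -0.37 (SE 0.08). DDIT3, which encodes the stress transcription factor CHOP, fell by -2.83 (SE 0.73). Without control replicate 2 the median was -0.24 with 11 lower members (adjusted p = 0.00171), and there were 4 lower members without control replicate 1 and 2, 3 and 3 without overexpressing replicates 1, 2 and 3. In each of these 4 cases no member was higher.

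**Figure D3:**
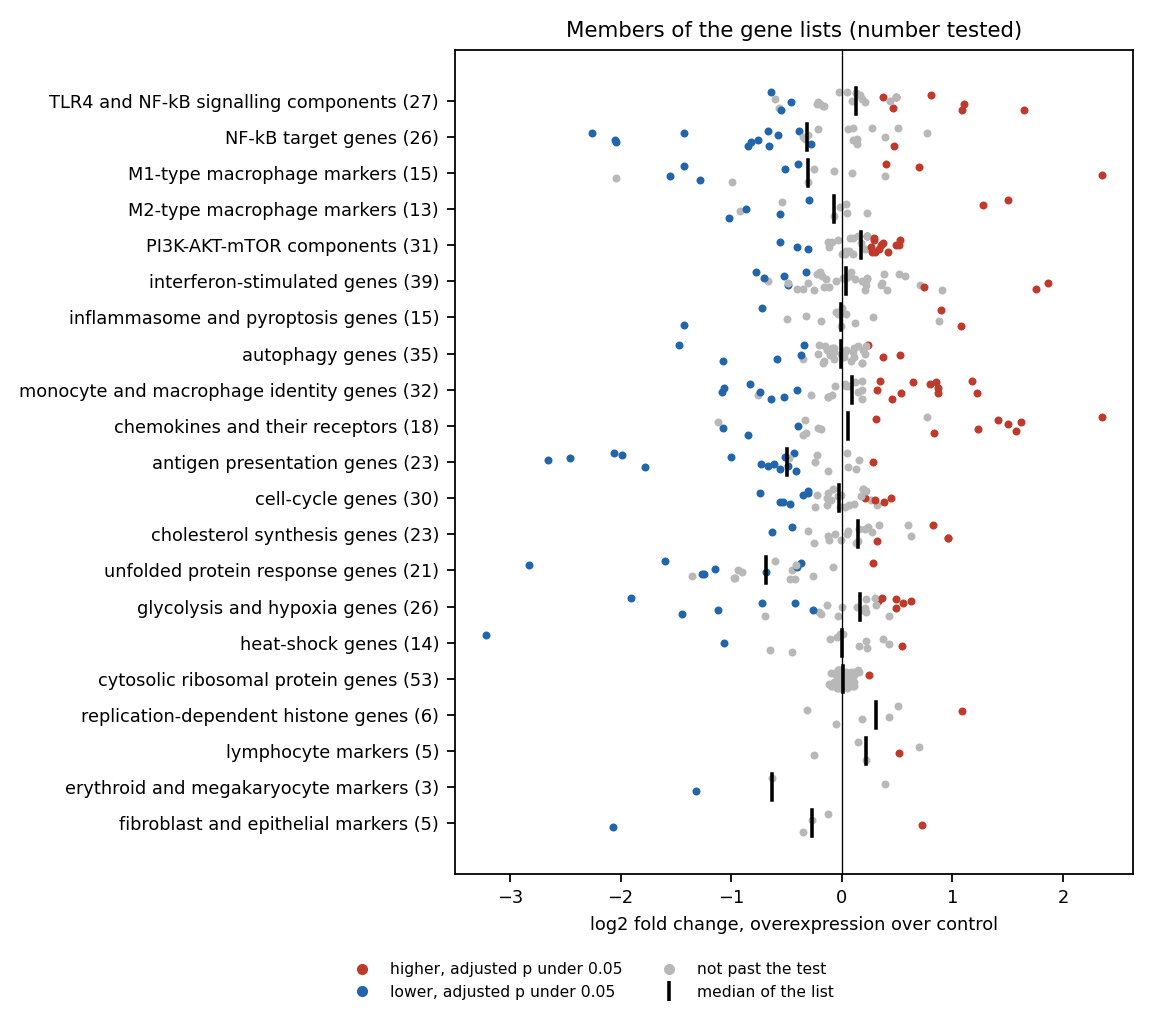
Log2 fold change of overexpression over control (horizontal axis) for the tested members of 21 gene lists (rows, with the number tested); points are genes, red where higher and blue where lower at a limma adjusted p under 0.05, grey otherwise, and black bars are list medians. The median was -0.49 for antigen presentation genes and -0.69 for unfolded protein response genes, the 2 lists that passed the set test at the preset correlation and did not pass with an estimated one (adjusted p = 0.934 for both).

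Metabolic and proliferation genes changed singly. Of 26 glycolysis and hypoxia genes, 6 were higher and 6 lower (8 and 6 over the list alone), among them the glycolytic gene TPI1 at log2 0.55 (SE 0.09) and the neuronal enolase gene ENO2 at -1.45 (SE 0.21); the median (0.17) and the set test pointed up and the mean (-0.09) down (camera adjusted p = 0.789). Of 23 cholesterol synthesis genes, 4 were higher (among them TM7SF2 and LSS) and 2 lower (STARD4 and HSD17B7), with a median of 0.15 that turned to -0.18 without control replicate 2, when 8 were lower (adjusted p = 0.555 with all libraries; 2 and 2 over the list alone). TM7SF2, a sterol reductase gene, rose by log2 0.82 (SE 0.09) and STARD4, a sterol transport gene, fell by -0.63 (SE 0.08). Of 30 cell-cycle genes, 4 were higher (TYMS, MCM2, MCM7 and PLK1) and 7 lower, with the same counts over the list alone (median -0.02, adjusted p = 0.713; median 0.04 without control replicate 3 and 0.02 without overexpressing replicate 1). RRM2, a subunit gene of ribonucleotide reductase, fell by log2 -0.74 (SE 0.09) and the mitotic kinase gene AURKB by -0.56 (SE 0.09). Higher cell-cycle genes numbered 0 without overexpressing replicate 2 or 3, 2 without control replicate 1 and 8 without control replicate 3. Lower ones numbered 4 without control replicate 1 or overexpressing replicate 1 or 2, and 12 without control replicate 2. Higher cholesterol genes numbered 1 without overexpressing replicate 1 and 2 without control replicate 1 or overexpressing replicate 2 or 3, and lower ones 1 without control replicate 1 or overexpressing replicate 3.

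Among heat-shock genes, falls were seen in HSPA6 (log2 -3.22, SE 0.46) and HSPA1B (-1.06, SE 0.19), whose reads can be shared with HSPA1A. DNAJA1 was the 1 of 14 that rose (0.54), a call that ended without any overexpressing library (limma adjusted p = 0.0757 to 0.108) or control replicate 1 (0.0513). Adjusted over the list alone, 0 were higher and 2 lower (median log2 0.00, camera adjusted p = 0.804), and there were 2 higher and 5 lower without control replicate 2 and 4 higher without control replicate 3. The median was 0.02, 0.08 and 0.04 without control replicate 1, control replicate 3 and overexpressing replicate 1. Of 53 cytosolic ribosomal protein genes, 52 did not pass, and RPL6 stood at 0.24 (limma adjusted p = 0.04; 0 when adjusted over the list alone), a call that ended without control replicate 1 or any overexpressing library (0.059 to 0.157), with DESeq2 (0.052) and with upper-quartile (0.0862), library-size (0.0585) or, in limma, TMM (0.0506) and library-size scaling (0.0551). Among 6 tested histone genes, H2BC12 rose by 1.09 (SE 0.27; 1 over the list alone), except without overexpressing replicate 1 (adjusted p = 0.0562). Markers of other cells were sparse. Of 17 lymphocyte markers 5 were tested, with NKG7 higher (log2 0.52, SE 0.15), a call that ended without any overexpressing library (0.0665 to 0.0842). Of 15 erythroid and megakaryocyte markers 3 were tested, with ITGA2B lower (-1.31, SE 0.23), and 2 lower without control replicate 2 or overexpressing replicate 1. Of 16 fibroblast and epithelial markers 5 were tested, with COL1A1 lower (-2.07, SE 0.46, from 254 ± 185 normalized counts in the controls) and PDGFRB higher (0.73, SE 0.26), the latter lost on leaving out any library but control replicate 3, and past the threshold in no count-based test (edgeR adjusted p = 0.0563). Adjusted over the list alone, these 3 lists had 1 and 0, 0 and 2, and 1 and 1 higher and lower members, and none passed as a set (camera adjusted p = 0.555, 0.493 and 0.684), nor did the heat-shock, ribosomal (0.73) and histone (0.555) lists.

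The authors' deposited table calls 1522 genes different, 541 higher and 981 lower, each with a q-value under 0.05 and at least a 2-fold change. Of these, 1293 were tested with limma and 1245 were called in the same direction, 48 were not called and none was called in the opposite direction; the other 229 in the authors' deposited table lay below the filter on low values. At the transcript level, 32719 of 87529 tested transcripts changed, 16401 higher and 16318 lower (limma, adjusted p under 0.05; 20160 and 20220 without overexpressing replicates 2 and 3). Reads were counted in several transcripts of a gene, so these calls largely repeat those of the genes: 5017 of the 5715 genes with a changed transcript were also called as genes. In 4 genes, DNAH14, ZNF451, BEST1 and ANKRD10, transcripts changed at least 1.5-fold in opposite directions. ZNF451 transcript XM_011514463.2 rose from 202 ± 34.0 to 391 ± 11.1 normalized counts (SD, n = 3; log2 0.96, SE 0.13) while XM_011514462.3 fell from 1234 ± 129 to 758 ± 12.4 (log2 -0.70, SE 0.09), and the gene as a whole fell by -0.40 (SE 0.07).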

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

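The edgeR fit with TMM, the pseudocounts, the limma scalings, the correction and the thinning were chosen after seeing the data. The count of 5793 changed genes ranged from 5563 to 5864 over filters, scalings, pseudocounts, correction, thinning, limma-voom and DESeq2 (5629), and a CPM filter or no filter gave 2886 or 2950 higher genes. It was 1269 (491 higher, 778 lower) at 2-fold and more, and 2940 (1494 and 1446) at an adjusted p under 0.01, as stricter criteria must give. Leaving out 1 library gave 3542 to 6684 changed genes (1732 to 3461 higher, 1810 to 3223 lower) and 20160 to 37190 changed transcripts; fewer libraries were tested, and the rise without control replicate 2 or 3 had no cause tested. Of the genes called with all libraries, 60.6% were also called in the same direction without overexpressing replicate 3 and 95.2% without control replicate 2. The replicate number as a block gave 5679 changed genes, 32124 changed transcripts and 2 lists; same-numbered libraries deviated together with correlations of 0.0921, 0.0421 and -0.00388, so the numbers were not read as pairs. The gene list tests called 2 lists, and with an estimated correlation 0 (unadjusted p under 0.05 for none of the 21). Antigen presentation at -0.491 and unfolded protein response at -0.688 both had an adjusted p of 0.934 there. The estimated correlations (0.119 and 0.774) exceed the preset. The 1 list that fry called was antigen presentation. Leaving out 1 library gave 2 to 4 lists, with medians from -0.537 to -0.455 for antigen presentation and -0.928 to -0.242 for unfolded protein response. Deposited values carry size factors, so RLE for lists was not run apart from them. Of the named genes, CXCL8 ranged from -0.5424 to 0.109 (-0.21 with all libraries), turning only without control replicate 2; the cause was not tested. The 97 genes of the naming rule and B2M, CD74 and PSMB8 were followed through the alternatives. Of their values, 1949 stayed on their side of the threshold with their direction, 78 calls were lost and 3 gained. Most of these genes were named because they passed, so the pooled count does not measure reliability. Leaving out control replicates 1, 2 and 3 lost 10, 2 and 1 calls, and leaving out overexpressing replicates 1, 2 and 3 lost 13, 11 and 14. Genes under 10 normalized counts are limited by depth.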

Other observations

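The tests of GC content and length, of chromosomes, of control replicate 2 and both tests of HLA reads, and the scan of gene families, were chosen after the results they bear on were seen. Gene families were taken from the letters that open a symbol, which gave 102 families with at least 15 tested members. The HLA family was the 1 past the threshold (camera adjusted p = 6.93e-07 over the families): 16 of 19 members were lower and 0 higher, with a median of log2 -0.73, though the p was 0.0609 with an estimated correlation. DEAD-box RNA helicase genes (DDX) came next, with 18 of 40 higher and 3 lower (median 0.21, adjusted p = 0.0691, and 0.00803 without control replicate 2), then syntaxin genes (STX), with 8 of 18 lower and 1 higher (median -0.30, adjusted p = 0.0691). Zinc-finger genes (ZNF) had 118 of 498 lower and 58 higher (median -0.17, adjusted p = 0.104). Mitochondrial ribosomal protein genes of the large subunit (MRPL) had 18 of 53 higher and 3 lower (median 0.14, adjusted p = 0.174), and golgin genes (GOLGA) 10 of 26 lower and 0 higher (median -0.16, adjusted p = 0.156, and 0.0488 without control replicate 2). HSP70 genes (HSPA) had 6 of 15 lower and 0 higher (median -0.56, adjusted p = 0.234, and 0.0488 without control replicate 2). Without control replicate 2 the camera adjusted p was 0.113 for STX, 0.145 for ZNF and 0.157 for MRPL genes. With an estimated correlation and all libraries the adjusted p was 0.851 for each of these 7 families.

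The fall of antigen presentation genes was weighed against technical sources; the list passed at the preset correlation and not with an estimated one (p = 0.0545). A first test, of the 10 members outside the HLA family, did not decide whether reads shared between HLA genes made it: their median was -0.0406, with 2 lower and 1 higher. A test of the HLA sum was added after that outcome, with HLA values already seen: reads moved from 1 HLA gene to another would leave the sum in place, but the 22 HLA rows together fell from 54617 ± 2814 to 36842 ± 1146 normalized counts (SD, n = 3), a log2 ratio of -0.568, with each overexpressing library below each control. After a correction of each library for GC content and transcript length the median of the list was -0.524 and the camera adjusted p 3.05e-05 at the preset correlation. Control means within the HLA sum were 25498 for HLA-B, against 509 for HLA-DRA and 40.8 for HLA-DPB1, so abundant genes set the sum. The sum argues against moved reads as the whole cause of the fall in the HLA total. It cannot decide this for class II genes with low counts. The correction argues against base composition as the whole cause. The circRNA and other differences between the cultures stay open, untested.

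The fall of unfolded protein response genes was weighed against control replicate 2, which had the highest values. At the preset correlation the list passed (camera adjusted p = 0.00113, and 0.00171 without that library). It did not pass with an estimated correlation (camera p = 0.355) or with fry (p = 0.117). Without control replicate 2, 11 of 21 members were lower in the gene test and the median was -0.242. The fall of those members therefore does not rest on that library alone, while that library sets much of the size of the fall. After the GC and length correction the median was -0.698 (adjusted p = 0.00206 at the preset correlation), which argues against that bias as the whole cause. The list mean ranged over 1.39 log2 units among the controls and 0.0637 among the overexpressing libraries, and control replicate 2 also had the highest share of mitochondrial rRNA reads (1.326%). Differences between the control cultures and the overexpression itself stay open, untested.

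The breadth of the change, 5793 genes, was weighed against depth, base composition and chromosome copy number. Thinned to the smallest library total, 95.8% of the called genes, or 96.2% of those that still passed the filter, were called again in the same direction, and after the GC and length correction 96.9% of the called genes that had a GC value were. No chromosome with at least 100 genes had a median log2 fold change beyond 0.0728 in size, where copy number differences of several chromosomes were set to need more than 0.2. The overlapping totals, the correction and the chromosome medians argue against depth, base composition and whole-chromosome copy number, in that order, as the whole cause. Gains or losses of parts of a chromosome, which could leave its median in place, were not tested. The circRNA and other differences between the sets of cells, such as separate transductions or passages, stay open, untested.

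The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 5793 genes and 32719 transcripts, as many as 1 of the 10 splits (itself) in both cases, and the highest of the other splits called 0 of each. Every other split mixed both groups on each side, so the group difference entered its residual spread. A low count there follows from that mixing and does not measure chance. For the gene lists, 10 of the 10 splits called at least the 2 lists of the real split, and the highest of the others called 10. The list calls at the preset correlation therefore cannot be set apart from those of other splits. Because these splits still carry part of the group difference, this comparison is not with chance alone.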
